A study of Mus musculus with 24 samples.

How the data were processed

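RNA from mouse retinas was measured on an Affymetrix array focused on glycan-related genes, with 24 arrays in 8 groups of 3: normal mice and mice with the P347S mutation at 1, 2, 3 and 4 months. Per the labels, total RNA was extracted with Trizol and biotinylated cRNA was hybridised. The deposited values are log2 expression values that the authors made with RMA, per the labels, which give no more than this name; the steps and version of RMA, the arrays normalized together and any filter on probe sets are not stated. That the scale is log2 was checked on the values, which ran from 1.9 to 14.17 with near-equal array medians (5.15 to 5.34). Nothing was scaled again in the main analysis.

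The file held 1246 probe sets, no array controls and no missing values, and all were tested. Gene names came from the transcript accession in each probe set name, matched to a table of RefSeq genes: 963 probe sets matched 909 genes, and 283 stayed unnamed, 261 of them with UCSC identifiers. Of the named genes 48 had several probe sets. Probe sets whose suffix marks probes that may be shared with other transcripts (237 with suffix s, 38 with suffix x and 91 with suffix a) were kept.

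Groups were compared in R 4.3.3 with limma 3.58.1. One linear model with a mean for each of the 8 groups was fitted to all 24 arrays (lmFit and eBayes with default settings, 16 residual degrees of freedom, prior degrees of freedom 4.37). Contrasts were mutant minus normal at each age, the mean of these 4 differences, a moderated F test of whether the difference changes with age, the difference at 4 months minus that at 1 month, and 4 months minus 1 month within each genotype. Tests were 2-sided, with Benjamini-Hochberg adjustment over the 1246 probe sets within each contrast and a threshold of 0.05. Errors are standard errors of limma's moderated estimate. Probe sets whose 3 mutant and 3 normal arrays did not overlap were counted as well. Groups of 3 cannot reach an exact p under 0.1, so calls at 1 age rest on limma's model of the spread.

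Of 39 gene lists written from general knowledge 31 had at least 3 measured genes and were tested with camera at a preset inter-gene correlation of 0.01, on 1 probe set per gene (the one with the highest mean), adjusted over the 31 lists. They were galectins, siglecs, C-type lectins, selectins and ligands, sialyltransferases, fucosyltransferases, N-glycan processing, N-glycan precursor, O-GalNAc synthesis, O-mannosylation, chondroitin and heparan sulfate synthesis, proteoglycan core proteins, hyaluronan, glycosphingolipid synthesis, lysosomal degradation, nucleotide sugar synthesis and transport, chemokines and their receptors, interleukins and related ligands, cytokine receptors, growth factors and their receptors, the Notch pathway, cell adhesion, ER lectins, mucins, and markers of microglia, reactive Müller glia and endothelium. Some lists share members, for example Icam1 and Vcam1 in the glial and adhesion lists, Csf1r in the microglial and cytokine receptor lists, Cx3cr1 in the microglial and chemokine receptor lists, Fgf2 in the glial and growth factor lists and Mcam in the adhesion and endothelial lists. Marker lists describe genes that move in whole retina and assign no cells. Members were counted at an adjusted p over all probe sets and adjusted over the list alone.

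Named genes followed a rule. At each age it takes the 10 largest rises and 10 largest falls among probe sets that passed without overlap between genotypes, and over the 4 ages the 15 largest of each with the same sign at every age. For the changes of the difference with age it takes the 8 with the smallest p, and for age within a genotype the 5 largest rises and falls. It also takes Lgals1 and Lgals3, and up to 4 members of each list described, by smallest p. Where none passed it takes the 3 with the smallest p, and unnamed probe sets are not named. The groups, contrasts, lists, this rule and the alternatives below were chosen before the data were examined, except where stated.

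Alternatives were each array centred on its median, quantile normalization again, probe sets below the 25th percentile (log2 3.83) or the median (5.26) of mean signal left out, an intensity trend or robust fit in eBayes, array weights, only the arrays of the groups compared, the replicate number as a block, an adjusted p under 0.01, an absolute log2 difference of at least 0.5, and each array left out in turn. Lists were also tested with an estimated correlation, with fry, and with the mean of all probe sets of a gene. After seeing the data 3 were added: without 3 arrays with a log2 Grifin signal above 10, with the log2 Grifin and Dcn signals as covariates, and at 2 months the 6 arrays alone with the replicate number as a block. Whether equal replicate numbers pair the arrays was checked by correlating, over probe sets, the deviations of same-numbered mutant and normal arrays from their group means: r was above 0.1 in 3 of 12 pairs, all at 2 months. The same-numbered normal array was the best match in 7 of 12 pairs, among them every pair of 2 months and of 4 months (r of 0.06 to 0.08 at 4 months). In the main fit the numbers were treated as labels only, so its p values at 2 months ignore this pairing.

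The model was tested on simulated data with changes placed in known probe sets. The simulated noise was normal and independent between probe sets and between arrays. Real arrays can share deviations, so the false calls given here do not measure the rate in these data. At 4 months it recovered 80.2% of changes of 0.5 and 96.3% of changes of 1 (log2), with 8 false calls among 186; over the 4 ages 95.9% and 98.1% (6 of 200), for 4 months against 1 month 74.2% and 95.3% (4 of 175), and for the interaction 53.5% and 91.9% (6 of 151). A shift of 0.4 in the microglial list was called with 0 of the other lists. Counts were compared with other assignments of the arrays, all 10 splits for 6 arrays and 100 drawn ones for larger designs. For the interaction the residuals of an additive model of genotype and age were also reassigned, within each genotype or in same-numbered pairs. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.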

Results

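Retinas of normal mice and of mice with the P347S mutation, a transgenic line in which rod photoreceptors die slowly, were profiled at 4 ages from 1 to 4 months. Each genotype and age had 3 arrays, 24 in all. The focused array held 1246 probe sets, and 963 of them could be matched to 909 mouse genes, mostly for glycan synthesis, glycan binding, cytokines, growth factors and their receptors. Values are log2 RMA signals between 1.9 and 14.17, and array medians lay between 5.15 and 5.34. The number of arrays limits the precision. The labels do not say whether the arrays of a group came from separate animals, so every p measures only the spread between samples. Gnb1 was the only measured gene of the rod list, so the share of rods could not be read from these arrays.

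Grifin, a galectin-related gene known from the lens, set 3 arrays apart. It read 11.33 in normal retinas of 2 months replicate 2, 11.29 in mutant retinas of 2 months replicate 2 and 10.16 in normal retinas of 4 months replicate 1, against 5.69 to 8.77 in the other 21 arrays. The 8.77 was read in normal retinas of 1 month replicate 1, while replicates 2 and 3 of that group read 5.80 and 6.01. That array was kept when the 3 arrays were left out. In those 3 arrays Lgals1 (galectin-1) read 9.38 to 9.89, Lgals3 (galectin-3) 7.75 to 8.44 and Cd44 8.19 to 9.23, against 8.32 to 9.38, 6.30 to 7.45 and 6.28 to 8.63 in the others. Dcn (decorin), a proteoglycan of connective tissue, was highest in normal retinas of 2 months replicate 3 (6.90), mutant retinas of 4 months replicate 3 (6.51) and normal retinas of 2 months replicate 2 (6.45). Counts without the 3 arrays, and with the Grifin and Dcn signals as covariates, stand beside the results below; both alternatives were chosen after seeing the data.

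**Figure D1:**
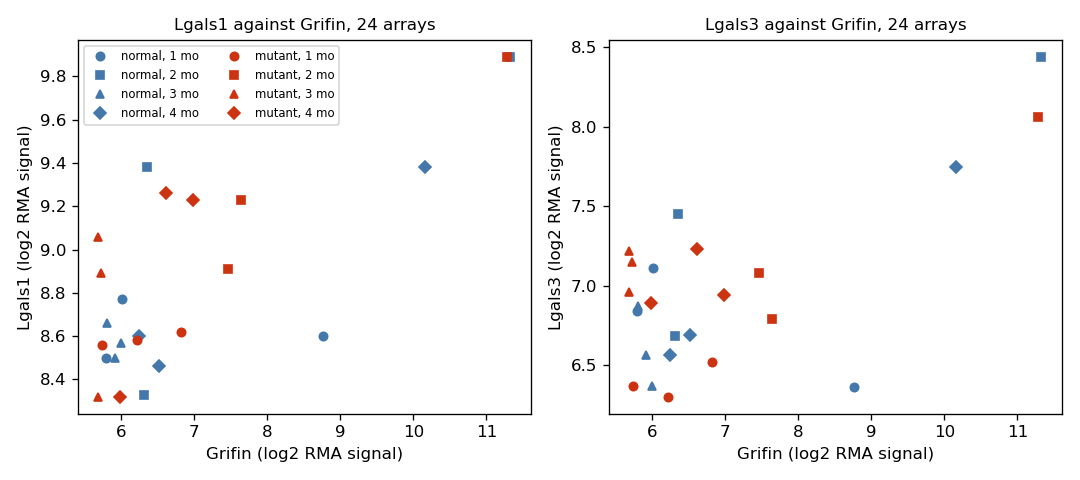
Log2 RMA signal of Lgals1 and of Lgals3 against that of Grifin, 1 point per array, with color for genotype and shape for age. The 3 arrays with Grifin above 10 have Lgals3 signals of 7.75 to 8.44, above the 6.30 to 7.45 of the other 21.

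Genotype over the 4 ages. This comparison asks which glycan-related genes differ between mutant and normal retinas whatever the age. Glycam1, a mucin-like ligand of L-selectin, was 4.63-fold higher in mutant retinas (log2 difference 2.21 ± 0.27, SE, n = 24 arrays, adjusted p = 4.19e-06). Its probe set, like those of Cx3cr1, Lgals9, Met and St8sia1 below, has suffix s and may not be specific to the gene named. The same holds below for Lgals1, Lgals3, B3gnt2, Lamtor5, Papss2, Cks2, Dhh, Notch2, Fgf5, Bmp15 and Neu2 (suffix s) and for B3galt1 (suffix x). Members named for a list or family can have such suffixes too, for example Ust (s) and Siglech (x). In normal retinas Glycam1 read 3.45 to 5.14, where background is not known, so its fold is uncertain. Btc (betacellulin), a ligand of the EGF receptor family, was 3.00-fold higher (1.59 ± 0.12, adjusted p = 2.21e-08), and Sulf1, which removes 6-O-sulfates from heparan sulfate, 1.65-fold higher (0.72 ± 0.05, adjusted p = 1.36e-08). The microglial receptors Cx3cr1 (0.94 ± 0.10), Csf1r (0.89 ± 0.09) and Adgre1 (0.81 ± 0.10) rose, as did the leukocyte adhesion molecules Icam1 (1.00 ± 0.12) and Vcam1 (0.81 ± 0.08). Mean signals over all arrays were 4.42 for Icam1, 3.95 for Adgre1 and 4.28 for Cd48 and Clec2d, named below. These lie between the 25th percentile (3.83) and the median (5.26), where background is not known, so their folds are uncertain at every age. Man2a2, a mannosidase of N-glycan maturation, fell by 0.71 ± 0.12, Ext1, a heparan sulfate polymerase, fell by 0.61 ± 0.12 and Chst3, which sulfates chondroitin, fell by 0.56 ± 0.06.

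The remaining genes of the 15 largest rises were Cd44, the hyaluronan receptor (1.01 ± 0.25), Lgals9 (galectin-9, 0.72 ± 0.11), the growth factor receptor Met (0.70 ± 0.10), the transcription factor Junb (0.70 ± 0.12), the Wnt receptor Fzd7 (0.70 ± 0.10), the lymphocyte antigen Cd48 (0.69 ± 0.10) and the chemokine Cxcl12 (0.67 ± 0.08), whose second probe set read 0.04 and did not pass (adjusted p = 0.851). Among the 15 largest falls were also the integrin Itgae (-0.55 ± 0.16), the phospholipase A2 receptor Pla2r1 (-0.55 ± 0.05), the O-glycan initiating transferases Galnt4 (-0.51 ± 0.05) and Galnt10 (-0.36 ± 0.08), the transcription factor Prdm1 (-0.46 ± 0.07) and the Notch ligand Jag1 (-0.43 ± 0.05). The sialyltransferases St8sia1 (-0.43 ± 0.07) and St3gal1 (-0.34 ± 0.07), the prefoldin subunit Pfdn6 (-0.30 ± 0.08), the N-glycan branching enzyme Mgat1 (-0.30 ± 0.08), the scaffold gene Dlg1 (-0.30 ± 0.04) and the phosphomannomutase Pmm1 (-0.29 ± 0.07) fell as well. Cd44 was among the genes that were higher in the 3 arrays with a high Grifin signal, and its adjusted p was 0.00581, 2.30e-06 without them and 4.05e-06 with Grifin and Dcn as covariates. In limma, 282 of 1246 probe sets passed, 172 higher and 110 lower in mutant retinas, and 211 of them had the same sign at all 4 ages; 47 of the 282 have no gene name. With the arrays quantile normalized again the higher share of the calls went from 61.0% to 50.6% (161 higher, 157 lower), and with each array centred on its median it went to 70.3%. Leaving out the 3 arrays gave 224 calls, without Itgae (adjusted p = 0.0609), and the covariates gave 294.

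**Figure D2:**
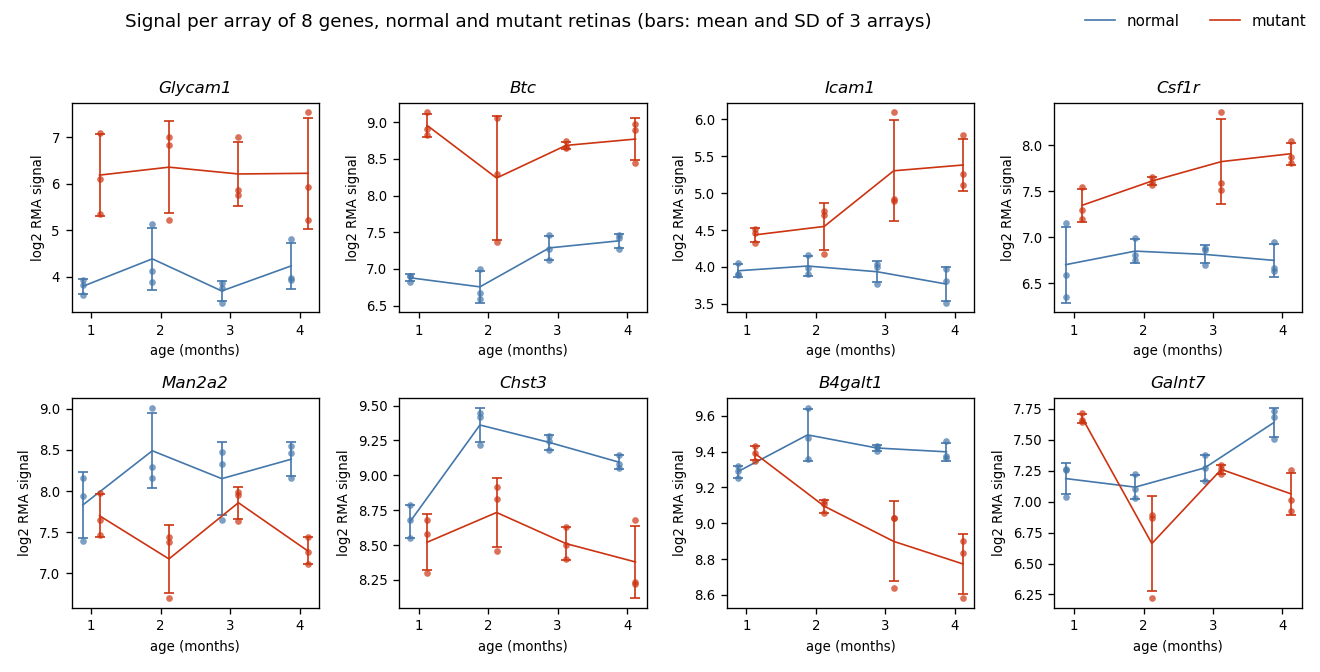
Log2 RMA signal of 8 genes by age in months, normal retinas in blue and mutant retinas in red; points are arrays, bars the mean and SD of 3 arrays. Btc differed at 1 month already (log2 difference 2.08), while B4galt1 differed by 0.10 at 1 month and -0.63 at 4 months.

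Camera called 4 fixed lists higher in mutant retinas over the 4 ages. The list for reactive Müller glia and astrocytes had 5 of its 24 genes measured. Gfap, Vim, Glul and Rlbp1 were not among them, so the list cannot be read as these cells alone. Of the 5 measured markers of reactive Müller glia and astrocytes, 4 rose (Vcam1, Icam1, Fgf2 and Cd44) and 1 did not pass (Lgals1), also 4 adjusted over the list alone; the mean difference was 0.65 (camera adjusted p = 0.00208; adjusted p = 0.325 with an estimated correlation). Of the 10 markers of microglia and macrophages, 4 rose (Csf1r, Cx3cr1, Adgre1 and Siglech, 0.40 ± 0.07), 0 fell and 6 did not pass, with 5 risen adjusted over the list alone (mean 0.33, camera adjusted p = 0.00574; adjusted p = 0.869 with an estimated correlation). Among 50 growth factors 16 rose, 0 fell and 34 did not pass, with 18 risen and 1 fallen adjusted over the list alone; Btc, Fgf13 (0.30 ± 0.05), Fgf2 (0.34 ± 0.05) and Pdgfc (0.24 ± 0.05) had the smallest p. The growth factor list had a mean of 0.12 and a camera adjusted p of 0.00574 (adjusted p = 0.869 with an estimated correlation). Of the 10 cell adhesion molecules 4 rose (Vcam1, Icam1, Cd48 and Mcam, an endothelial adhesion molecule) and 1 fell (Itgae), also 4 and 1 adjusted over the list alone (mean 0.25, camera adjusted p = 0.0496; adjusted p = 0.909 with an estimated correlation). Icam1 and Vcam1 are members of both the glial and the adhesion list, and Lgals1 and Cd44 moved with the Grifin signal as given above. No list call at any age held with an estimated correlation. The adhesion call ended with Grifin and Dcn as covariates (adjusted p = 0.0699), with probe sets below the 25th percentile of signal left out (0.119), with each array centred (0.0764), with the replicate number as a block (0.0589) and without 1 array in 13 cases, with adjusted p from 0.0501 to 0.106. These were normal retinas of 1 month replicates 2 (0.0605) and 3 (0.0633), mutant retinas of 1 month replicates 1 (0.0518) and 3 (0.0528), normal retinas of 2 months replicates 2 (0.0524) and 3 (0.0658), mutant retinas of 2 months replicates 1 (0.0505) and 3 (0.0882), normal retinas of 3 months replicates 1 (0.0744) and 3 (0.0700), normal retinas of 4 months replicates 1 (0.0501) and 3 (0.0622), and mutant retinas of 4 months replicate 1 (0.106).

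Genes of proteoglycan and glycosaminoglycan synthesis moved both ways. Of 24 heparan sulfate genes 7 rose, 3 fell and 14 did not pass, also 7 and 3 adjusted over the list alone, with Sulf1, Hs3st5 (0.25 ± 0.04) and Hs6st2 (0.34 ± 0.06) up and Ext1 down. Of 18 genes of chondroitin and dermatan sulfate synthesis 4 rose, 5 fell and 9 did not pass, also 4 and 5 adjusted over the list alone; Ust (0.39 ± 0.07) and Chst11 (0.25 ± 0.06), which are sulfotransferases, rose, while Chst3 and the chondroitin polymerase Chsy1 (-0.25 ± 0.06) fell. Of 30 proteoglycan core proteins 7 rose, 2 fell and 21 did not pass (8 and 2 adjusted over the list alone), among them Srgn (serglycin, 0.48 ± 0.09), Gpc3 (glypican-3, 0.46 ± 0.09) and Agrn (agrin, 0.31 ± 0.07) up and Gpc2 (-0.27 ± 0.06) down. Of 6 genes for hyaluronan 1 rose, Cd44, also 1 adjusted over the list alone. Camera called none of these lists (adjusted p = 0.490 for heparan sulfate, 0.782 for chondroitin sulfate, 0.474 for core proteins and 0.846 for hyaluronan).

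Sialyltransferases also split. Of 19 measured, 6 rose, 3 fell and 10 did not pass (8 and 4 adjusted over the list alone), with the polysialyl and oligosialyl transferase St8sia3 (0.45 ± 0.06) and St3gal4 (0.32 ± 0.07) up and St8sia1 and St6galnac2 (-0.30 ± 0.06) down. Of 25 genes of O-GalNAc glycan synthesis 5 rose, 2 fell and 18 did not pass, also 5 and 2 adjusted over the list alone; Galnt13 (0.50 ± 0.09) and Gcnt2 (0.34 ± 0.08) rose while Galnt4 and Galnt10 fell. Of 11 genes of N-glycan processing 2 rose, Mgat4c (0.28 ± 0.04) and Man2a1 (0.28 ± 0.07), and 2 fell, Man2a2 and Mgat1, also 2 and 2 adjusted over the list alone. Of 16 glycosphingolipid genes 6 rose, 1 fell and 9 did not pass (7 and 1 adjusted over the list alone), with B4galt5 (0.44 ± 0.06) and Ugcg (0.28 ± 0.05), which make lactosylceramide and glucosylceramide, and St6galnac5 (0.32 ± 0.08) up and St8sia1, the GD3 synthase, down. Of 10 fucosyltransferases 2 rose, Fut8 (0.25 ± 0.05) and Fut9 (0.29 ± 0.06), and 3 fell, among them Fut7 (-0.21 ± 0.04) and Fut2 (-0.15 ± 0.04; its second probe set read -0.04 and did not pass), also 2 and 3 adjusted over the list alone. The camera adjusted p was 0.383 for sialyltransferases, 0.782 for O-GalNAc and N-glycan processing genes, 0.249 for glycosphingolipid genes and 0.635 for fucosyltransferases.

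In the other enzyme lists the counts adjusted over the list alone were those over all probe sets. Of 14 genes of the N-glycan precursor 0 rose and 2 fell adjusted over the list alone and over all probe sets, Alg10b (-0.24 ± 0.05) and Dad1 (-0.15 ± 0.05). Of 9 genes of dystroglycan O-mannosylation Pomt2 (-0.27 ± 0.07) fell, of 5 ER lectin and quality control genes Uggt1 (-0.26 ± 0.08) fell, and of 18 nucleotide sugar transporters Slc35d3 (0.28 ± 0.06) rose; each stayed at 1 adjusted over the list alone. Of 34 nucleotide sugar synthesis genes 4 rose and 4 fell, with Papss1 (0.18 ± 0.04) and Ugp2 (0.16 ± 0.04) up and Gfpt1 (-0.20 ± 0.05) and Pmm1 down. Of 21 lysosomal glycan degradation genes 5 rose and 2 fell, and the sulfatases Arsb (0.38 ± 0.06) and Arsa (0.24 ± 0.06), the amidase Aga (0.31 ± 0.05) and prosaposin Psap (0.17 ± 0.04) had the smallest p. None of 9 mucins passed. Camera adjusted p was 0.474 for the N-glycan precursor, 0.249 for O-mannosylation, 0.635 for the ER genes, 0.846 for the transporters, 0.852 for nucleotide sugar synthesis, 0.361 for lysosomal genes and 0.554 for mucins.

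Lectins and signalling genes completed the lists. Of 9 galectins 1 rose, Lgals9, and of 9 siglecs Siglech rose and Siglec15 (-0.12 ± 0.04) fell, unchanged in number adjusted over the list alone (camera adjusted p = 0.852 and 0.806). Of 46 C-type lectins 3 rose and 4 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.383), with Chodl (0.39 ± 0.07), Clec2d (0.55 ± 0.11) and Clec4a3 (0.18 ± 0.05) up and Cd207 (-0.17 ± 0.05) down. Of 7 selectins and ligands Glycam1 and Cd34 (0.32 ± 0.07) rose (2 risen and 1 fallen adjusted over the list alone, camera adjusted p = 0.820). Of 24 growth factor receptors 8 rose and 2 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.132), with Egfr (0.45 ± 0.05), Acvr1 (0.53 ± 0.07), Tgfbr2 (0.64 ± 0.09) and Met up; the second probe sets of Tgfbr2 (-0.004) and Egfr (-0.002) did not pass. Of 35 cytokine receptors 10 rose and 1 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.249), with Csf1r, Il10rb (0.41 ± 0.07), Il6st (0.39 ± 0.07) and Il1r1 (0.37 ± 0.08) up. Of 29 chemokines 5 rose and 1 fell, Cxcl12 (by 1 of its 2 probe sets), Ccl12 (0.63 ± 0.12) and Cxcl13 (0.27 ± 0.07) up and Pf4 (-0.17 ± 0.05) down, and of 20 chemokine receptors 2 rose, among them Cx3cr1, unchanged adjusted over the list alone (camera adjusted p = 0.554 and 0.635).

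Of 32 interleukins, interferons and TNF family ligands 4 rose and 1 fell, also 4 and 1 adjusted over the list alone, with Csf1 (0.34 ± 0.05), Il33 (0.45 ± 0.11) and Il18 (0.17 ± 0.05) up and Il27 (-0.16 ± 0.05) down (camera adjusted p = 0.782). Of 17 Notch pathway genes 3 rose and 2 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.895): Notch1 (0.56 ± 0.07), Notch2 (0.40 ± 0.08) and Hes1 (0.21 ± 0.06) rose while Jag1 fell. Of 8 endothelial and pericyte markers Mcam (0.34 ± 0.06) and Cd34 rose, also 2 adjusted over the list alone (camera adjusted p = 0.386). The list mean and the test differed in sign for galectins (mean 0.04, median -0.01, tested lower), siglecs (0.01, -0.02, lower), chemokine receptors (0.01, -0.06, lower), interleukins (0.01, -0.03, lower) and N-glycan processing (-0.01, 0.04, higher). For selectins (mean 0.31, median -0.02), heparan sulfate genes (0.05, -0.01) and Notch genes (0.02, -0.05) the median alone was negative. Too few genes were measured to test 8 lists. Toll-like receptors, complement, cone markers and bipolar and amacrine markers had 0, rod markers 1 (Gnb1), ganglion cell markers 1 (L1cam), pigment epithelium and choroid markers 2 (Dcn, Lum), and lens, cornea and blood markers 2 (Ppbp, Pf4).

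**Figure D3:**
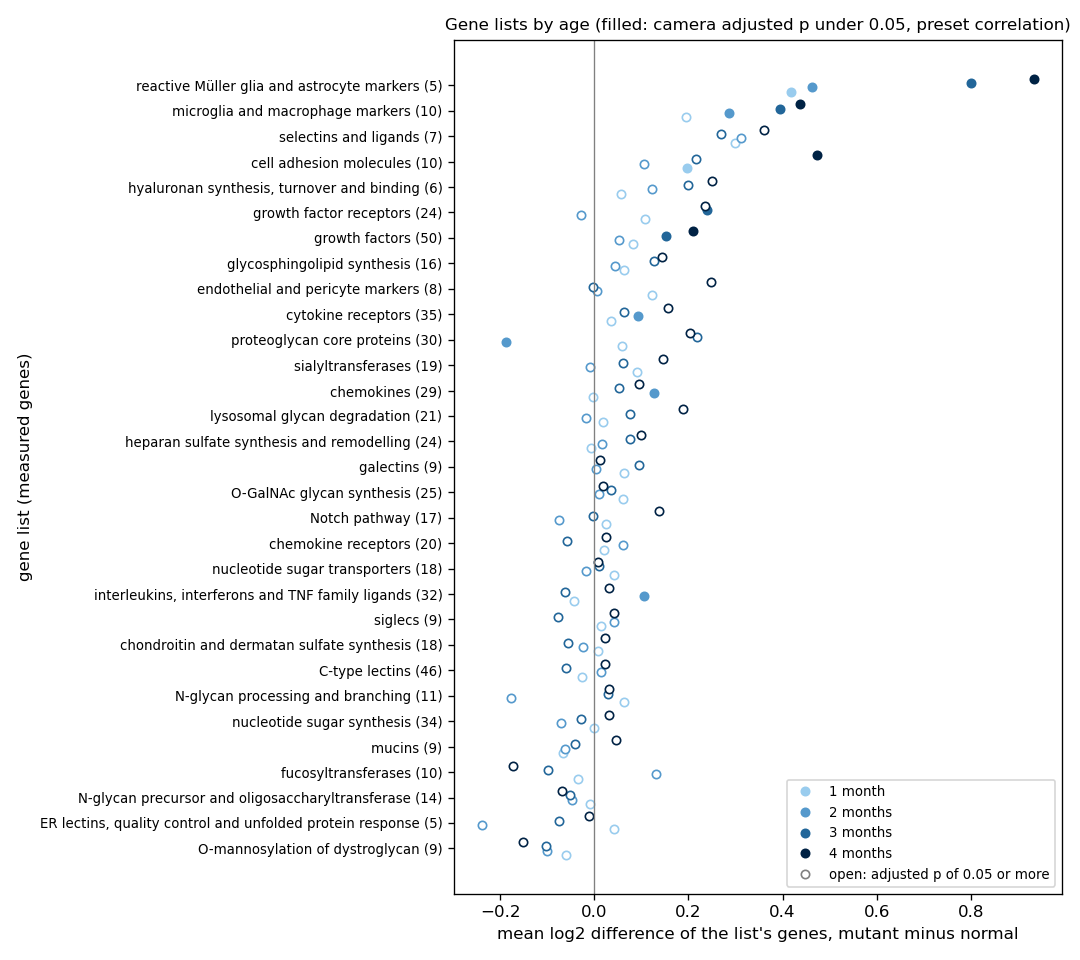
Mean log2 difference, mutant minus normal, of the measured genes of 31 lists at each age, with the number of measured genes in brackets; filled points had a camera adjusted p under 0.05 at the preset correlation of 0.01. The reactive Müller glia list is filled at all 4 ages, with means from 0.42 at 1 month to 0.94 at 4 months.

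Galectins at each age. The study's stated background names galectin-1 and galectin-3, so both are given whatever their test. Both probe sets have suffix s and may not be specific to these genes. The Lgals1 difference was -0.04 ± 0.33 at 1 month, 0.14 ± 0.33 at 2 months, 0.18 ± 0.33 at 3 months and 0.12 ± 0.33 at 4 months, and 0.10 ± 0.16 over the 4 ages (adjusted p = 0.673). Lgals3 differed by -0.38 ± 0.36, -0.21 ± 0.36, 0.51 ± 0.36 and 0.02 ± 0.36 at the 4 ages and by -0.01 ± 0.18 over them (adjusted p = 0.96). Neither passed at any age, and both read higher in the 3 arrays with a high Grifin signal than in most others. The model shares its spread between ages, so these arrays also enter the errors at 1 and 3 months. Neither gene passed at any age without the 3 arrays or with Grifin and Dcn as covariates. Over the 4 ages Lgals3 then differed by 0.10 (limma adjusted p = 0.518) and 0.0587 (0.751). At 3 months Lgals3 read 6.96 to 7.22 in mutant and 6.37 to 6.87 in normal arrays, without overlap. At the other ages the genotypes overlapped. At 4 months normal replicate 1, with a high Grifin signal, read 7.75, against 6.56 and 6.69 in the other normal arrays. The Lgals3 tests therefore do not show that it is unchanged. Lgals9, a galectin of immune cells, rose by 0.72 ± 0.11 over the 4 ages (adjusted p = 7.47e-05) and by 0.90 ± 0.22 at 4 months (adjusted p = 0.00916).

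Genotype at 1 month. This age stands for the early stage of the degeneration. Btc was 4.22-fold higher in mutant retinas (log2 difference 2.08 ± 0.25, SE, n = 3 arrays per group, limma adjusted p = 6.39e-05). Sulf1 was 1.64-fold higher (0.72 ± 0.11, adjusted p = 8.38e-04) and Mcam 1.59-fold higher (0.67 ± 0.11, adjusted p = 0.0036). Glycam1, named here after its values were seen, differed by 2.38 ± 0.54 and did not pass (adjusted p = 0.0545). All 3 named genes passed without any 1 of the 6 arrays, without the 3 arrays with a high Grifin signal and with Grifin and Dcn as covariates. Normal replicate 1 of this age, with Grifin at 8.77, is not among those 3 arrays, but is 1 of the 6 left out in turn.

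In total 4 of 1246 probe sets passed at 1 month, 3 higher and 1 lower, the last without a gene name, and 115 had an unadjusted p under 0.05, where chance gives 62. Centring each array gave 10 calls, 90.0% of them higher, and quantile normalization 8 calls, 87.5% higher, against 75%. Array weights gave 52 calls (36 higher, 16 lower) and a fit of only the 6 arrays of this age 28 (25 and 3). Both groups of arrays did not overlap for 22.1% of probe sets, where chance gives 10%. The 5 markers of reactive Müller glia had a mean of 0.42, with 0 passing and 2 risen adjusted over the list alone: Vcam1 0.56 ± 0.17 and Fgf2 0.36 ± 0.10 had the smallest p (camera adjusted p = 0.0143; adjusted p = 0.673 with an estimated correlation). Of the 10 adhesion molecules Mcam rose, and 2 rose adjusted over the list alone (mean 0.20, camera adjusted p = 0.032; adjusted p = 0.866 with an estimated correlation). The 10 microglial markers had a mean of 0.19, with 0 passing and 4 risen adjusted over the list alone (camera adjusted p = 0.0774); Adgre1 differed by 0.77 ± 0.20 (adjusted p = 0.0903). Of these 2 list calls 1 was left without normal retinas of 1 month replicate 2, 1 without replicate 3 of that group (with 2 other lists called) and 1 without mutant retinas of 1 month replicate 1. Neither was left with each array centred or with probe sets below the 25th percentile of signal left out. The count was 6 without the 3 arrays and 5 with the covariates.

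Genotype at 2 months. Microglial receptors were higher at this age: Cx3cr1, the fractalkine receptor, was 2.11-fold higher (1.08 ± 0.20, n = 3 arrays per group, adjusted p = 0.00463) and Csf1r 1.69-fold higher (0.76 ± 0.19, adjusted p = 0.0244). Glycam1 (1.97 ± 0.54, adjusted p = 0.0462) and Btc (1.48 ± 0.25, adjusted p = 0.00299) were also higher. Man2a2 fell by 1.31 ± 0.25 (adjusted p = 0.00502), Papss2, which makes the sulfate donor PAPS, fell by 0.97 ± 0.23 and Pla2r1 fell by 0.57 ± 0.10 (adjusted p = 0.00463). The other named rises were B3gnt2 (0.54), Acvr1 (0.50), Sulf1 (0.49), Lamtor5 (0.45), Smo (0.43) and B3galt1 (0.42). The other named falls were Prdm1 (-0.67), Chst3 (-0.63), Cox18 (-0.60), Ovgp1 (-0.59), Jag1 (-0.54), Pomt2 (-0.50) and Magi2 (-0.49).

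In total 43 probe sets passed, 19 higher and 24 lower, with 17.4% of probe sets not overlapping where chance gives 10%. Both replicate 2 arrays of this age carried the high Grifin signal, and Dcn read 6.45 and 6.90 in normal replicates 2 and 3 against 4.23 to 4.78 in the mutant arrays. Without the 3 arrays 1 probe set passed in limma, none of the 20 named genes and 125 at an unadjusted p under 0.05; with Grifin and Dcn as covariates 6 passed, Btc and Pla2r1 among the named genes. Same-numbered arrays of both genotypes deviated together at 2 months (r = 0.33, 0.66 and 0.25 across probe sets, which are not independent replicates). With the replicate number as a block, 32 probe sets passed in the model of all arrays, and 16 in the 6 arrays of this age alone, 11 of them among the 43. The first block ended the calls of Smo (adjusted p = 0.0614), B3galt1 (0.0626) and Pomt2 (0.0572); in the 6 arrays Glycam1, Cx3cr1, Csf1r, Man2a2 and Prdm1 passed and the other 15 named genes had adjusted p from 0.0615 to 0.174. The fit of the 6 arrays was chosen after seeing the data. Array weights gave 68 calls, and a fit of only the 6 arrays of this age without a block gave 2. Leaving out normal replicate 1 gave 62 calls (18 higher, 44 lower), normal replicate 2 gave 22, normal replicate 3 gave 14 and mutant replicate 2 gave 16. Without mutant replicate 3 there were 22 higher and 21 lower, 28 of them among the main calls. Btc, Cx3cr1, Man2a2, Ovgp1 and Pla2r1 passed without any 1 array, and each of the other 15 lost its call without at least 1, with its direction kept: the differences ran from 0.71 to 0.83 for Csf1r, 0.44 to 0.47 for Lamtor5, 0.48 to 0.60 for B3gnt2, -0.72 to -0.59 for Prdm1, 1.64 to 2.53 for Glycam1 and -1.31 to -0.68 for Papss2. Without normal replicate 3 the adjusted p was 0.205 for Glycam1, Acvr1, Smo and Pomt2, 0.156 for Papss2, 0.0881 for Lamtor5 and 0.0575 for Jag1. Without mutant replicate 2 it was 0.189 for B3galt1, 0.17 for Magi2, 0.131 for Cox18, 0.0744 for Sulf1, 0.0667 for Chst3 and 0.0549 for Prdm1, and without normal replicate 2 it was 0.0981 for Csf1r and 0.113 for B3gnt2.

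At 2 months 5 lists were called higher and 1 lower, all with an adjusted p of 0.873 with an estimated correlation. Of 10 microglial markers Cx3cr1 and Csf1r rose, and 6 rose adjusted over the list alone (mean 0.29, camera adjusted p = 0.0413). The 5 markers of reactive Müller glia had 0 passing and 2 risen adjusted over the list alone, with Vcam1 at 0.58 ± 0.17 (mean 0.46, camera adjusted p = 0.0413). Chemokines had 0 of 29 passing over all probe sets and adjusted over the list alone, with Cxcl10 at 0.40 ± 0.13 and Ccl12 at 0.66 ± 0.24 (mean 0.13, camera adjusted p = 0.0413). Of 32 interleukins and related ligands Csf1 rose by 0.39 ± 0.10, also 1 adjusted over the list alone (mean 0.10, camera adjusted p = 0.0413), and of 35 cytokine receptors Csf1r rose, also 1 adjusted over the list alone (mean 0.09, camera adjusted p = 0.0477). Proteoglycan core proteins were called lower with 0 of 30 passing and 1 risen and 3 fallen adjusted over the list alone (mean -0.19, camera adjusted p = 0.0452). In that list Tgfbr3 differed by -0.63 ± 0.18, Gpc2 by -0.39 ± 0.11, Sdc4 by -0.47 ± 0.15 and Dcn, with the signals given above, by -1.48 ± 0.51. Of these 6 list calls, 0 to 3 were left without any 1 array of this age: 0 without mutant replicate 2, 1 without normal replicate 1 or normal replicate 3, 2 without mutant replicate 3 and 3 without normal replicate 2 or mutant replicate 1. Leaving out the 3 arrays left 2 list calls, and leaving out probe sets below the 25th percentile of signal left 1.

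Genotype at 3 months. Glycam1 was 5.69-fold higher in mutant retinas (2.51 ± 0.54, n = 3 arrays per group, adjusted p = 0.00496) and Icam1 2.58-fold higher (1.37 ± 0.24, adjusted p = 0.00152). Glycam1 read 3.45 to 3.88 in the normal arrays, near the 25th percentile of signal (3.83), so the size of its fold is uncertain. The fold of Icam1, with a mean of 4.42 over all arrays, is uncertain too. Btc (1.40 ± 0.25), Met (1.03 ± 0.21), Csf1r (1.01 ± 0.19), Cxcl12 (0.98 ± 0.17), Adgre1 (0.94 ± 0.20), Cx3cr1 (0.92 ± 0.20), Fzd7 (0.90 ± 0.20) and Tgfbr2 (0.89 ± 0.18) were also higher; the second probe sets of Tgfbr2 (-0.003) and Cxcl12 (0.03) did not pass. Galnt4 fell by 0.78 ± 0.11 (adjusted p = 4.05e-04), Chst3 fell by 0.72 ± 0.13 (adjusted p = 0.00155) and B4galt1, which adds galactose to N-glycans, fell by 0.52 ± 0.10 (adjusted p = 0.00174). The cell cycle gene Cks2 (-0.62 ± 0.18), the hedgehog ligand Dhh (-0.59 ± 0.18), Jag1 (-0.58 ± 0.11), St8sia1 (-0.56 ± 0.15), Prdm1 (-0.56 ± 0.14), Wnt9b (-0.54 ± 0.09) and Galnt10 (-0.52 ± 0.16) fell too; the second Dhh probe set read -0.45 and did not pass (adjusted p = 0.0525).

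In total 150 probe sets passed, 83 higher and 67 lower, and 32.6% did not overlap where chance gives 10%. After quantile normalization of the arrays again 88 were higher and 97 lower. The higher share was 55.3% in the main fit, 47.6% after that step and 61.8% with each array centred on its median. None of the 3 arrays with a high Grifin signal is of this age; without them 136 passed and Galnt10 did not (adjusted p = 0.0529). With the covariates 111 passed, without Cks2 (0.0889), Dhh (0.0829) and Galnt10 (0.0557). Leaving out 1 array gave 81 calls without normal replicate 1 (57 higher, 24 lower), 69 without normal replicate 2 (40 and 29), 76 without mutant replicate 2 (61 and 15) and 66 without mutant replicate 3 (38 and 28). A fit of only the 6 arrays of this age gave 40 calls (30 higher, 10 lower). Of the 20 named genes 14 passed without any 1 array. The differences of the other 6 kept their direction, from 0.62 to 1.06 for Fzd7, -0.74 to -0.45 for St8sia1, -0.65 to -0.35 for Galnt10, -0.75 to -0.51 for Cks2, -0.69 to -0.52 for Dhh and -0.70 to -0.41 for Prdm1. Fzd7 lost its call without mutant replicate 3 (adjusted p = 0.0549) and St8sia1 without normal replicate 1 (0.0992), normal replicate 3 (0.0611), mutant replicate 2 (0.0656) or mutant replicate 3 (0.0581). Mutant replicate 2 ended the calls of Galnt10 (0.201), Cks2 (0.136), Dhh (0.123) and Prdm1 (0.0612). Normal replicate 1 ended those of Galnt10 (0.126), Dhh (0.117) and Cks2 (0.0872), normal replicate 2 those of Galnt10 (0.0848) and Cks2 (0.0593), normal replicate 3 those of Cks2 (0.0740), Dhh (0.0639) and Prdm1 (0.0558), mutant replicate 1 that of Cks2 (0.0626) and mutant replicate 3 that of Dhh (0.0960).

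At 3 months 4 lists were called higher. Of 5 reactive Müller glia markers Icam1, Vcam1 (0.82 ± 0.17) and Fgf2 (0.39 ± 0.10) rose, 4 adjusted over the list alone (mean 0.80, camera adjusted p = 0.0073; adjusted p = 0.519 with an estimated correlation). The other 3 calls had an adjusted p of 0.925 with an estimated correlation. Of 10 microglial markers Csf1r, Adgre1, Cx3cr1 and Siglech (0.46 ± 0.13) rose, also 4 adjusted over the list alone (mean 0.39, camera adjusted p = 0.0303). Of 50 growth factors 5 rose and 0 fell, also 5 adjusted over the list alone, with Btc, Fgf2, Fgf13 (0.31 ± 0.09) and Tgfb2 (0.39 ± 0.12) in front (mean 0.15, camera adjusted p = 0.0303). Of 24 growth factor receptors 6 rose and 1 fell (6 and 2 adjusted over the list alone), with Egfr (0.67 ± 0.11; second probe set 0.07, not passing), Acvr1 (0.68 ± 0.13), Tgfbr2 and Met up (mean 0.24, camera adjusted p = 0.0376). Of 24 heparan sulfate genes 6 rose, among them Sulf1 (0.75 ± 0.11) and Hs3st1 (0.42 ± 0.09), and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.240). Of the 4 list calls 1 was left without normal replicate 1, 1 without mutant replicate 1, 1 with Grifin and Dcn as covariates and 0 with probe sets below the 25th percentile of signal left out.

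Genotype at 4 months. This is the latest stage profiled. Icam1 was 3.06-fold higher in mutant retinas (1.61 ± 0.24, n = 3 arrays per group, adjusted p = 1.56e-04) and Vcam1 2.46-fold higher (1.30 ± 0.17, adjusted p = 7.92e-05). Icam1 had a mean of 4.42 over all arrays, where background is not known, so its fold is uncertain. Glycam1 (1.99 ± 0.54, adjusted p = 0.0161), Btc (1.39 ± 0.25), Csf1r (1.16 ± 0.19), Cx3cr1 (1.12 ± 0.20), Fzd7 (1.04 ± 0.20), Tgfbr2 (0.98 ± 0.18), the C-type lectin Clec2d (0.98 ± 0.21) and Met (0.96 ± 0.21) were higher; the second Tgfbr2 probe set read -0.07 and did not pass. Man2a2 fell by 1.11 ± 0.25 (adjusted p = 0.00441), Cks2 fell by 0.92 ± 0.18 and Ext1 fell by 0.84 ± 0.24 (adjusted p = 0.0209). Pla2r1 (-0.74 ± 0.10), Chst3 (-0.72 ± 0.13), Galnt4 (-0.71 ± 0.11), St8sia1 (-0.64 ± 0.15), B4galt1 (-0.63 ± 0.10), St3gal1 (-0.59 ± 0.14) and Galnt7 (-0.58 ± 0.13) fell too.

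In total 161 probe sets passed, 118 higher and 43 lower (73.3% higher), and 30.0% did not overlap where chance gives 10%. After quantile normalization of the arrays again 100 were higher and 87 lower (53.5% higher), and with each array centred on its median 79.9% of the calls were higher. The count was 116 without the 3 arrays and 158 with the covariates; all 20 named genes passed under both. Without normal replicate 3 of this age 107 passed, and in a fit of only its 6 arrays 103. Leaving out 1 array ended the call of Glycam1 without normal replicate 2 (adjusted p = 0.0610), normal replicate 3 (0.0708) or mutant replicate 1 (0.12). It ended that of Ext1 without normal replicate 2 (0.0999), normal replicate 3 (0.0819), mutant replicate 1 (0.0615) or mutant replicate 3 (0.0601). With each of the 6 arrays left out in turn their differences ran from 1.33 to 2.49 for Glycam1 and from -1.04 to -0.69 for Ext1.

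At 4 months 4 lists were called higher, each with an adjusted p of 0.821 with an estimated correlation. Of 5 reactive Müller glia markers Vcam1 and Icam1 rose, and 4 rose adjusted over the list alone; Cd44 differed by 1.39 ± 0.50 and did not pass (mean 0.94, camera adjusted p = 0.0122). Of 10 microglial markers Csf1r, Cx3cr1 and Adgre1 (0.84 ± 0.20) rose, 4 adjusted over the list alone (mean 0.44, camera adjusted p = 0.014). Of 50 growth factors 11 rose and 0 fell, also 11 adjusted over the list alone, with Fgf13 (0.51 ± 0.09), Btc, Fgf1 (0.74 ± 0.16) and Pdgfc (0.40 ± 0.10) in front (mean 0.21, camera adjusted p = 0.0122). Of 10 adhesion molecules Vcam1, Icam1 and Cd48 (0.75 ± 0.20) rose, 5 adjusted over the list alone (mean 0.47, camera adjusted p = 0.014). Of 19 sialyltransferases 4 rose, among them St8sia3 (0.70 ± 0.11) and St6gal1 (0.53 ± 0.11), and 3 fell, among them St6galnac4 (-0.35 ± 0.07) and St8sia1 (10 and 4 adjusted over the list alone, camera adjusted p = 0.406). Of 24 growth factor receptors 9 rose, with Egfr (0.88 ± 0.11; second probe set 0.15, not passing), Gfra2 (0.60 ± 0.11) and Tgfbr2 among the smallest p, and 1, Bmpr1a (-0.48 ± 0.09), fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.118). Grifin read 10.16 in normal replicate 1 of this age and 5.99 to 6.98 in the 3 mutant arrays.

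Calls shared between ages. Of the 83 probe sets higher at 3 months and the 118 higher at 4 months, 63 were the same, where independent draws would share 7.9, and of the 67 and 43 lower ones 24 were shared, where 2.3 would be. None was called in opposite directions at these ages. Of the 19 higher at 2 months 16 were higher at 3 months and 16 at 4 months, and of the 24 lower ones 14 and 14 were. Independent draws would share 1.3 and 1.8 of the higher and 1.3 and 0.8 of the lower ones. All ages share 1 estimate of the spread per probe set, so independent draws are too low a baseline for each of these overlaps. Differences between ages were tested only by the interaction contrasts that follow.

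Genotype by age. This comparison asks whose genotype difference changed with age. Galnt7, an O-glycan initiating transferase, differed by 0.49 ± 0.13 at 1 month and by -0.46 ± 0.13, -0.01 ± 0.13 and -0.58 ± 0.13 at 2, 3 and 4 months (limma F = 13.6, adjusted p = 0.0344). Egfr differed by 0.21 ± 0.11, 0.04 ± 0.11, 0.67 ± 0.11 and 0.88 ± 0.11 (F = 13.1, adjusted p = 0.0344), while its second probe set did not pass (F = 1.47, adjusted p = 0.573; 0.15 at 4 months). The differences were, for the TGF-beta co-receptor Tgfbr3, 0.18 ± 0.18, -0.63 ± 0.18, 0.81 ± 0.18 and 0.55 ± 0.18 (F = 12.2, adjusted p = 0.0357). B4galt1 differed by 0.10 ± 0.10, -0.40 ± 0.10, -0.52 ± 0.10 and -0.63 ± 0.10 (F = 11.4, adjusted p = 0.0419). These 4 were the only probe sets to pass of 1246, with 180 at an unadjusted p under 0.05, and Lgals1 (F = 0.089) and Lgals3 (F = 1.17) did not. In limma 0 passed without the 3 arrays (130 at an unadjusted p under 0.05), 0 with the covariates (115) and 0 with the replicate number as a block (173). The 4 genes then had adjusted p from 0.105 to 0.268, from 0.118 to 0.187 and from 0.0618 to 0.0834. The count was 0 without normal retinas of 1 month replicates 1 or 3, mutant retinas of 1 month replicate 1, normal retinas of 2 months replicates 2 or 3, normal retinas of 3 months replicate 1 or any 1 of the 3 normal arrays of 4 months. It was 1 without mutant retinas of 1 month replicate 2 or of 2 months replicates 2 or 3, 2 without normal retinas of 3 months replicate 3, 7 without mutant retinas of 3 months replicates 1 or 3, 9 without mutant retinas of 2 months replicate 1 and 31 without normal retinas of 2 months replicate 1. Array weights gave 51 calls.

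Late against early difference. The difference at 4 months minus that at 1 month was -1.06 ± 0.19 for Galnt7 (adjusted p = 0.0152), -0.73 ± 0.13 for B4galt1 (adjusted p = 0.0166) and -0.48 ± 0.10 for Fryl (adjusted p = 0.0348). For Fryl, whose protein is related to the fly gene furry, the genotype difference was 0.01 ± 0.07 at 1 month and -0.47 ± 0.07 at 4 months. In limma 3 probe sets passed, all lower, with 142 at an unadjusted p under 0.05, and camera called 0 of 31 lists (3 at an unadjusted p under 0.05), while the mixed test of fry called 4. Lgals1 (0.16 ± 0.46) and Lgals3 (0.40 ± 0.51) did not pass. Centring each array gave 6 calls (16.7% higher) and quantile normalization 15 (53.3% higher), against 0.0% of the 3. Leaving out the 3 arrays gave 0 calls, with 120 at an unadjusted p under 0.05 (adjusted p of 0.0561 for Galnt7 and 0.0646 for B4galt1 and Fryl), and the covariates gave 2, without Fryl (0.0529). The count was 0 without normal retinas of 1 month replicate 3 or of 4 months replicate 2, 6 without normal retinas of 1 month replicate 2 or of 4 months replicate 1 and 24 without mutant retinas of 4 months replicate 3. Array weights gave 81 calls (54 higher, 27 lower) and a fit of only the 12 arrays compared 12 (4 and 8). Galnt7 and B4galt1 had adjusted p of 0.0527 and 0.0748 without the first 2 of these arrays. Fryl lost its call without 8 of the 12 arrays, with adjusted p up to 0.113: normal retinas of 1 month replicates 2 and 3 (0.0649 and 0.0916), mutant retinas of 1 month replicates 1, 2 and 3 (0.0820, 0.0936 and 0.0573), normal retinas of 4 months replicates 2 and 3 (0.104 and 0.1) and mutant retinas of 4 months replicate 2 (0.113). Without any 1 array the difference ran from -0.53 to -0.42 for Fryl, -1.16 to -0.99 for Galnt7 and -0.79 to -0.63 for B4galt1.

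Age in mutant retinas. From 1 to 4 months the decoy receptor Il13ra2 rose by 1.17 ± 0.17 (n = 3 arrays per group, adjusted p = 9.21e-04) and Egfr by 0.70 ± 0.11 (adjusted p = 0.00104; second probe set 0.11, not passing). Notch2 (0.91 ± 0.17), Icam1 (0.95 ± 0.24) and Fgf5 (0.69 ± 0.16) rose too. The Il13ra2 probe set had a mean of 3.28 over all arrays, below the 25th percentile of signal (3.83). It may lie near background, so the size of its rise is uncertain. The sizes of the rises of Icam1 and Fgf5 are uncertain too, with means of 4.42 and 4.03 over all arrays. B4galt1 fell by 0.62 ± 0.10 (adjusted p = 0.00104), Prdm1 fell by 0.68 ± 0.14, Bmp15 fell by 0.83 ± 0.20, Galnt7 fell by 0.61 ± 0.13 and Chsy1 fell by 0.56 ± 0.12. In total 33 probe sets passed, 19 higher and 14 lower at 4 months; centring each array gave 22, of which 45.5% were higher against 57.6%. The count was 31 without the 3 arrays and 30 with the covariates, where Icam1 (adjusted p = 0.0642) and Bmp15 (0.0641) did not pass. Leaving out 1 mutant array gave 13, 9 and 16 calls without replicates 1, 2 and 3 of 1 month (6, 5 and 12 higher), and 18 and 15 without replicates 1 and 2 of 4 months (8 and 8 higher). Of the 10 named genes Il13ra2, Notch2, Egfr and B4galt1 passed without any 1 array. The differences of the others kept their direction, from 0.75 to 1.09 for Icam1, 0.65 to 0.74 for Fgf5, -1.02 to -0.71 for Bmp15, -0.78 to -0.54 for Prdm1, -0.71 to -0.54 for Galnt7 and -0.60 to -0.47 for Chsy1. Array weights gave 94 calls (65 higher, 29 lower). Without replicate 2 of 1 month the adjusted p was 0.136 for Icam1, 0.130 for Fgf5 and Bmp15, 0.0690 for Prdm1 and 0.0631 for Galnt7. Replicate 1 of 1 month ended the calls of Icam1 and Fgf5 (0.0929), Bmp15 (0.0794) and Galnt7 (0.0660), and replicate 3 of 1 month those of Icam1, Bmp15 and Chsy1 (0.0768) and Fgf5 (0.0564). At 4 months replicate 1 ended those of Icam1 (0.163), Fgf5 (0.0992), Prdm1 and Galnt7 (0.0537), replicate 2 those of Bmp15 (0.0992), Galnt7 (0.0785), Fgf5 (0.0698) and Chsy1 (0.0582), and replicate 3 those of Bmp15 (0.0797) and Fgf5 (0.0534).

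Age in normal retinas. No gene passed in limma between 1 and 4 months, with 92 probe sets at an unadjusted p under 0.05 where chance gives 62. Fryl (0.34 ± 0.07, adjusted p = 0.0853), Pla2r1 (0.40 ± 0.10, adjusted p = 0.262) and the sialidase Neu2 (-0.30 ± 0.08, adjusted p = 0.262) had the smallest p. Lgals1 differed by 0.19 ± 0.33 and Lgals3 by 0.23 ± 0.36, and limma gave 0 calls without the 3 arrays (90 at an unadjusted p under 0.05) and with the covariates (78). With an intensity trend in the variance Fryl passed (adjusted p = 0.0341), and with array weights 26 probe sets did, among them Pla2r1 (0.0109), Fryl (0.0152) and Neu2 (0.0152). That genes passed in mutant and not in normal retinas does not show a difference between them; the contrast of late against early differences above tests it.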

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

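The tests of explanations and of other splits of the arrays in this part were chosen only after the results were seen; the interaction tests were planned.

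The difference between mutant and normal retinas changed with age for 4 genes by limma's interaction test: Galnt7 (F = 13.55), Egfr (F = 13.08), Tgfbr3 (F = 12.22) and B4galt1 (F = 11.37). Galnt7 moved from 0.49 at 1 month to -0.58 at 4 months, Egfr from 0.21 to 0.88 (by 1 of 2 probe sets; the other had F = 1.472, adjusted p = 0.573), B4galt1 from 0.10 to -0.63, and Tgfbr3 was -0.63 at 2 months and 0.81 at 3 months. Tgfbr3 at 2 months belongs to the age with the high Grifin and Dcn signals. Of 100 assignments of arrays to ages within each genotype, the real one included, 2 gave 4 or more calls (real 4, highest other 5); these assignments also move the effect of age into the spread. With the additive effects of genotype and age removed and residuals reassigned, 1 of 100 did (highest other 2), and 3 of 100 with same-numbered pairs kept together (highest other 9), which argues against chance for the count. The count was nevertheless 0 without the 3 arrays with a high Grifin signal, with Grifin and Dcn as covariates, with the replicate number as a block and without 9 of the 24 arrays in turn, so which genes change with age stays open. With 1 array left out in turn F ran from 10.64 to 25.21 for Galnt7 and from 10.99 to 17.84 for Egfr. It ran from 9.35 to 21.17 for Tgfbr3 and from 8.77 to 15.13 for B4galt1.

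The difference at 4 months minus that at 1 month was set apart from 0 for Galnt7 (-1.06), B4galt1 (-0.73) and Fryl (-0.48). Of 100 assignments of the arrays of 1 and 4 months 6 gave 3 or more calls (real 3, highest other 13), so chance cannot be excluded for this count.

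For the other comparisons, reassigning arrays to genotypes within each age gave 282 or more calls over the 4 ages in 1 of 100 assignments, the real one (highest other 155), which argues against chance. The 4 list calls over the 4 ages were matched or exceeded in 11 of 100 assignments (highest other 8), so chance cannot be excluded for them. Splits of 6 arrays number 10, too few for a share under 0.05. The real counts and the highest others were 4 and 0 at 1 month, 43 and 1 at 2 months, 150 and 1 at 3 months, 161 and 1 at 4 months, 33 and 0 for age in mutant retinas, each reached by 1 of 10 splits, and 0 and 0 for age in normal retinas, reached by 10 of 10.

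A high Grifin signal marked 3 arrays. The lower of the 2 replicate 2 arrays of 2 months lay 3.64 above the highest other array of that age (pooled SD 0.81 within the groups without such arrays). Arrays of 1 genotype and age thus lay this far apart, which argues against genotype or age as the whole cause, although the arrays were picked for this signal. The groups behind the pooled SD include normal retinas of 1 month, where replicate 1 read 8.77 against 5.80 and 6.01 in replicates 2 and 3. Of 10 other genes that stood above the rest in both replicate 2 arrays (B3gnt5, Cd44, Fgfr3, Ggta1, Igfbp7, Lgals1, Lgals3, Pgm5, Wnt7a and Wnt7b), 10 were also higher in replicate 1 of normal retinas at 4 months than in the other 2 arrays of that group, which is consistent with tissue of another kind in the dissected retina. Its kind stays open, because of the fixed list for lens, cornea and blood only Ppbp and Pf4 were measured.

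Btc, Sulf1 and Mcam were higher in mutant retinas at 1 month. A lower share of rod RNA would raise the markers of other cell types alike, and 23 of them had a median of 0.06 (SD 0.32). The smallest of the 3 differences was 0.67, but the 3 genes were picked because they passed, so they had to lie above such a median. The comparison therefore cannot decide whether a lower share of rods added to their rise. Carry-over measured by Grifin and Dcn is argued against by an adjusted p of 0.00795 or less for each gene with both as covariates. A response of the mutant retina remains a hypothesis that may explain the rise, and was not tested otherwise.

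Camera called the markers of reactive Müller glia and of microglia higher over the 4 ages, with 4 of 5 and 4 of 10 genes passing and an adjusted p of 0.325 and 0.869 with an estimated correlation. A lower share of rod RNA would raise endothelial markers as well. The 5 glial genes had a median of 0.81 and 8 endothelial ones 0.05 (exact permutation of genes, 2-sided p = 0.00311). The 10 microglial genes had a median of 0.12 (exact permutation of genes, 2-sided p = 0.143). Genes are not independent replicates. Both marker lists were picked because camera had called them higher in the same arrays, so a gap from the endothelial list was likely beforehand. The comparison therefore cannot decide whether a lower share of rods added to the rise of either list. With Grifin and Dcn as covariates the camera adjusted p was 3.34e-04 and 0.00549, which argues against this carry-over as the whole cause, although Cd44 and Lgals1 of the glial list and Lgals3 of the microglial list are among the 10 genes above. More such cells, or more RNA of these genes per cell, may each explain the rise of the genes that passed, and the list calls themselves were not beyond other assignments of the arrays.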

How the results depend on the processing

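The tests without the 3 arrays with a high Grifin signal, with Grifin and Dcn as covariates and with a block in the 6 arrays of 2 months were chosen only after the results were seen. Counts below are probe sets that passed, and the cause of each change was not tested except where fewer arrays or a stricter threshold give it.

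At 1 month the count of 4 became 10 with arrays centred, 8 with quantile normalization, 7 without probe sets below the 25th percentile, 52 with array weights and 28 with only the arrays compared. At 2 months 43 became 68 with array weights, 2 with only the arrays compared, 1 without the 3 arrays, 6 with the covariates and 16 with the block in 6 arrays. Only the arrays compared gave 40 at 3 months, 103 at 4 months, 12 for 4 months against 1 month and 1 for age in normal retinas. Array weights gave 51 for the interaction, 81 for 4 months against 1 month, 26 for age in normal retinas and 94 in mutant retinas. The interaction count became 0 with the replicate block, without the 3 arrays and with the covariates. For 4 months against 1 month 3 became 6 with arrays centred, 15 with quantile normalization, 10 without probe sets below the median and 0 without the 3 arrays. An intensity trend gave 1 for age in normal retinas. An adjusted p under 0.01 left 13, 50 and 91 at 2, 3 and 4 months, 150 over the 4 ages, 0 for the interaction, 0 for 4 months against 1 month and 6 for age in mutant retinas. An absolute log2 difference of at least 0.5 left 21, 55 and 82 at 2, 3 and 4 months, 34 over the 4 ages and 19 for age in mutant retinas.

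Leaving out 1 array gave 3 to 4 calls at 1 month, 14 to 62 at 2 months, 66 to 148 at 3 months, 107 to 159 at 4 months, 237 to 344 over the 4 ages, 0 to 31 for the interaction, 0 to 24 for 4 months against 1 month, 0 to 0 for age in normal retinas and 9 to 35 in mutant retinas. List calls ran from 1 to 3, 0 to 3, 1 to 4 and 3 to 5 at the 4 ages and from 3 to 4 over them.

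With an estimated correlation 0 lists were called at each age and over the 4 ages. Directional fry called 0, 0, 1 and 6 at the 4 ages and 6 over them, and mixed fry 1, 10, 20 and 21 at the 4 ages and 27 over them. Leaving out probe sets below the 25th percentile gave 0, 1 and 0 list calls at 1, 2 and 3 months. Centring gave 0 at 1 month, leaving out the 3 arrays 2 at 2 months and the covariates 1 at 3 months.

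Signs changed only for results that had not passed. Lgals1 at 1 month was 0.0583 with the covariates, and Lgals3 at 4 months was -0.16 with quantile normalization. Lgals3 over the 4 ages was 0.0115 centred, 0.0572 with array weights, 0.10 without the 3 arrays and 0.0587 with the covariates. For age in normal retinas Lgals1 was -0.0902 and Lgals3 -0.15 without the 3 arrays, and -0.0243 and -0.0546 with the covariates. With arrays centred the list means over the 4 ages became 0.0134 for C-type lectins (0.0187 without probe sets below the 25th percentile), 0.0123 for N-glycan processing and branching, 0.0137 for chondroitin and dermatan sulfate synthesis and 0.0091 for nucleotide sugar synthesis. The mean of the siglecs became -0.00706 without the 3 arrays.

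Leaving out 1 array in turn changed the sign as well. Lgals1 ran from -0.0968 to 0.0359 at 1 month, from -0.29 to 0.49 at 2 months, from -0.0543 to 0.43 at 4 months, from -0.00593 to 0.19 over the 4 ages, from -0.0168 to 0.47 for 4 months against 1 month and from -0.0902 to 0.37 for age in normal retinas. Lgals3 ran from -0.63 to 0.24 at 2 months, from -0.20 to 0.39 at 4 months, from -0.12 to 0.10 over the 4 ages and from -0.15 to 0.45 for age in normal retinas. The list means over the 4 ages ran from -0.00541 to 0.0163 for siglecs, from -0.0267 to 0.00249 for N-glycan processing and branching and from -0.0293 to 0.00721 for chondroitin and dermatan sulfate synthesis. They ran from -0.00146 to 0.025 for chemokine receptors and from -0.00746 to 0.0159 for interleukins, interferons and TNF family ligands.

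Array controls kept in, and another offset before the logarithm, were not run, since the values held no controls and were log2 already. The arrays give no background signal, so it was not known which dim probe sets lay above background, and a count of 0 there does not show that a gene is unchanged.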

Other observations

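The families in this part were chosen only after their values were seen, as were their tests over the 4 ages.

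Beta-1,4-galactosyltransferases moved both ways. Of 7 measured, 3 rose (B4galt5 0.44, B4galt6 0.35 and B4galt4 0.24) and 3 fell (B4galt1 -0.36, B4galt3 -0.17 and B4galt7 -0.14), with 3 and 4 adjusted over the list alone; signs held under centring and quantile normalization, while B4galt7 did not pass when arrays were centred (adjusted p = 0.128) and B4galt6 not after quantile normalization (0.0642), where B4galt2 passed as lower (-0.22, adjusted p = 5.89e-04). Of 12 beta-1,3-galactosyl- and N-acetylglucosaminyltransferases 4 rose and 0 fell, among them B3gnt2 (0.56) and B3galt1 (0.55); after quantile normalization B3gnt9 did not pass (adjusted p = 0.399) and B3galt4 passed as lower (-0.22, adjusted p = 0.016). Of 10 BMP ligands 3 rose (Bmp15 0.39, Bmp3 0.35 and Bmp5 0.21) and 0 fell, also 3 and 0 adjusted over the list alone; Bmp5 did not pass after quantile normalization (adjusted p = 0.0815), while Bmp6 passed then (0.0385) and with arrays centred (0.0196). Of 9 Frizzled receptors Fzd7 (0.70) and Fzd1 (0.42) rose, and of 19 Wnt ligands Wnt5a (0.29) rose and Wnt9b (-0.28) and Wnt8b (-0.15) fell. Of 6 hedgehog pathway genes Smo (0.35) and Shh (0.23) rose and 0 fell, but Shh did not pass after quantile normalization (limma adjusted p = 0.0889). Of 7 IGF binding proteins Igfbp5 (0.29) rose and 0 fell. No passing member of these families changed sign under either scaling. Centring moves every difference by the same amount, and the smallest passing one, of B4galt7, went from -0.135 to -0.109. It could therefore turn no sign here, so only quantile normalization tested this.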
